A study of Mus musculus with 20 samples.

How the data were processed

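Splenic B cells of C57BL/6J mice aged 8 to 12 weeks were profiled by RNA-seq, per the labels. WT denotes wild-type cells and DKO denotes cells carrying CreERT2, floxed Tet2, floxed Tet3 and a Rosa26-LSL-YFP reporter, in which both TET dioxygenase genes had been acutely deleted, per the labels. Cells were collected unstimulated (0 h) or after 24, 48, 72 or 96 h with lipopolysaccharide (LPS, 25 µg/mL) and interleukin-4 (IL-4, 10 ng/mL). The 20 libraries formed 10 groups of 2, numbered replicate 1 and replicate 3 in the labels. The labels do not say whether the libraries of a group came from separate animals or cultures, so p-values measure the spread between these samples, which may be technical.

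Per the labels' protocols, 10 ng of total RNA was reverse transcribed with an oligo-dT primer and a template-switching oligonucleotide, amplified, and made into Nextera XT libraries with 12 PCR cycles. Libraries were read as 50 bp single-end reads on a HiSeq2500. This kit does not mark strand, so reads of a gene and of an overlapping antisense gene cannot be told apart, and short reads shared between near-identical genes are uncertain. Priming at poly(A) tails and PCR without molecular identifiers mean that reads are not independent molecules, so the spread between libraries, not the read number, sets the error here.

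The values are transcripts per 1000000 (TPM) as deposited by the authors, in a table from HISAT2 alignments and a table from TopHat alignments, each with 24500 gene entries and 20 library columns summing to 1000000. A further deposited column gives each gene's length in kb, and the TPM values were divided by it. The lengths run from 0.02 to 2270.7 kb and span introns, so deposited TPM values are low for genes with long introns and high for very short genes such as microRNA genes. The submitters' processing notes name HISAT2, TopHat2, HTSeq, edgeR, bcl2fastq 2.20.0.442 and the mm10 (GRCm38) mouse genome, without their roles. The annotation, the counting mode and any filters are not given in the sources used here. The ribosomal RNA gene Rn45s was inside the deposited total and took 16.0 to 47.0% of the TPM of a library, which lowers the TPM of all other genes in that library by a factor that differs between libraries.

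TPM multiplied by gene length gave whole multiples of a common step in each library, with 100% of the values within 0.02 of a whole number, so the number of reads per gene was recovered. The HISAT2 table held 5000018 to 8532717 reads per library (median 6815504), and the table from TopHat alignments held 3578342 to 6147760. Between 8854 and 10892 genes per library reached 1 TPM. A single read in a gene of 1 kb was worth 0.957 to 1.51 TPM, so 1 or 2 reads in a very short gene, such as a microRNA gene, give a high TPM.

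The tests used R 4.3.3 with limma 3.58.1; tables and plots used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. Genes with at least 1 TPM in at least 2 libraries of the HISAT2 table were kept (11544 genes). The limma model was fitted to log2(TPM + 1) with a mean for each of the 10 groups, all 20 libraries and a mean-variance trend, leaving 10 residual degrees of freedom. Fold changes are therefore on the log2(TPM + 1) scale, which understates the change of genes with low values. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called. Where no gene differs, a share of about 0.05 of the genes tested is expected at an unadjusted p under 0.05. The model has no term for the replicate number, so differences between replicates 1 and 3 widen the spread and raise the p-values. The 12 comparisons were DKO against WT at each of the 5 times, DKO against WT averaged over the 4 activated times, the change of that difference from 0 h, WT at each activated time against WT at 0 h, and WT at 96 h against 24 h.

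Of 35 gene lists, 30 had at least 5 tested members and were compared with all other genes by limma's camera test with a preset inter-gene correlation of 0.01, adjusted over the lists. Calls are printed with the adjusted p under a correlation estimated from the data without block or rescaling, at which no list was called in any comparison. Counts of list members past the threshold are given over all genes tested and, where stated, adjusted over the list alone. The 5 lists without a set test were immunoglobulin constant region genes and mitochondrially encoded genes (0 members in the table for both), erythroid markers (4 tested), sex-linked genes (2 tested) and germline and methylation-sensitive genes (1 tested).

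The design, the tests, the gene lists, the rule for named genes and 15 alternative settings were fixed before the data were examined. The rule took, per comparison, up to 8 genes with the largest rise and up to 8 with the largest fall among called genes with a mean of at least 5 TPM in the higher group and the same direction in replicates 1 and 3, without predicted gene models. It added Tet1, Tet2, Tet3, Aicda and up to 4 members per list described. Exceptions were made after the values had been seen. In the WT comparisons the text gives part of the genes the rule took, leaving out short RNA genes with few reads (Snord52, Mir425 and similar) and some protein-coding genes for length. Genes named outside the rule (Slc31a2, Cyb5r3 and Rnf138rt1) are marked where they appear. Gene coordinates are those of GENCODE vM21 on GRCm38, the mm10 build.

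The replicate numbers mark 2 library sets, which the labels name differently, so same-numbered libraries were treated as pairs in an alternative fit with the number as a block. This pairing was checked on the deviations of libraries from their group means: across genes, deviations of same-numbered libraries of any pair of groups correlated at 0.22 to 0.53 (median 0.35, 45 pairs of groups), and the second principal component (17.1% of the variance) separated the numbers. Libraries of 1 group differed far beyond counting noise (chi-square per degree of freedom 25.6 to 111.9, Pearson correlation across genes 0.914 to 0.962), so none was a repeated deposit.

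Alternatives changed the table, the pseudocount (0.1 or 5 TPM), the filter, the scaling (TPM divided by median-ratio size factors, 0.68 to 1.26, or quantile normalization), the variance model, the library weights, the block and the set test, and left out each library in turn. A further 5 were added after the data had been examined: rescaling with the block, a filter of at least 10 reads, limma's voom on the recovered reads with and without the block, and an exact sign-flip test of 4 genes over pairs.

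The limma procedure was tested on simulated data with 100 genes changed 2-fold and 100 changed 4-fold. The changed genes were drawn from genes with a mean of at least 5 TPM, so genes with lower values were not covered. For DKO against WT over the activated times (11583 genes) it recovered 52 and 92 of them, with 2 unchanged genes called. For DKO against WT at 48 h (11661 genes) it recovered 0 and 2, so the fit reported could miss most changes of this size at a single time. With the replicate block it recovered 1 and 39 there, with 2 unchanged genes called. For WT at 24 h against 0 h (11318 genes) it recovered 5 and 45, and with the block 27 and 85 with 10 unchanged genes called.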

Results

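RNA was measured in splenic B cells of 2 genotypes, WT and Tet2/Tet3-deleted (DKO), before and during activation with LPS, a bacterial ligand of TLR4, and IL-4, a cytokine that drives switching to IgG1 and IgE. Each of the 10 combinations of genotype and time had 2 libraries, replicates 1 and 3. The libraries held 5000018 to 8532717 reads assigned to genes, and between 8854 and 10892 genes reached 1 TPM. Values below are TPM as mean ± SD with n = 2, and fold changes are on the log2(TPM + 1) scale with the limma standard error (SE).

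Tet2 and Tet3 encode dioxygenases that oxidise 5-methylcytosine, and both were the targets of the deletion. Tet3 (chromosome 6, 83362373 to 83459084, minus strand, mm10) stood at 3.79 ± 1.26 TPM in WT and 1.98 ± 1.44 TPM in DKO cells at 0 h. At 24, 48, 72 and 96 h it stood at 2.87 ± 1.91, 2.90 ± 0.536, 2.87 ± 1.78 and 2.79 ± 1.44 TPM in WT and at 2.29 ± 1.41, 1.49 ± 0.866, 1.80 ± 1.21 and 2.26 ± 1.26 TPM in DKO. Tet2 (chromosome 3, 133463679 to 133545139, minus strand) stood at 3.55 ± 3.42 TPM in WT and 2.44 ± 2.99 TPM in DKO at 0 h. At the later times Tet2 stood at 2.54 ± 2.67, 4.31 ± 1.88, 4.05 ± 3.05 and 5.45 ± 5.51 TPM in WT and at 3.10 ± 2.38, 4.41 ± 1.98, 5.30 ± 3.70 and 4.90 ± 4.56 TPM in DKO. Over the activated times the Tet3 difference was -0.39 (SE 0.28) and the Tet2 difference 0.15 (SE 0.48), both at a limma adjusted p of 1. DKO libraries were below the WT library of the same number for Tet3 in 8 of 8 activated pairs (mean -0.39 ± 0.24 SD, exact sign-flip p = 0.0078, adjusted over 4 genes 0.016) and for Tet2 in 1 of 8 (0.15 ± 0.23, exact p = 0.12, adjusted 0.16). Tet1 stayed under 0.7 TPM in every library and was lower in DKO in 4 of 8 pairs (exact p = 0.69). The sign-flip test was chosen after the pairs had been seen, and 0.0078 is the smallest two-sided p it can give with 8 pairs. The pairs are 4 times of 2 replicate numbers, and times of a number may share animals, so they may not be independent. The values count reads over whole genes, and the labels do not give the deleted exons, so they do not check the deletion.

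The WT time course compared cells after 24 to 96 h with LPS and IL-4 with unstimulated cells at 0 h. No sample was cultured without LPS and IL-4, so effects of activation, of time in culture and of loss of other cells cannot be told apart. At 24 h the largest rise in WT cells under the naming rule was in a chemokine gene and the largest fall in an immediate early gene. The chemokine gene Ccl22 (chromosome 8, 94745590 to 94751699, plus strand) rose from 0.304 ± 0.153 to 246 ± 37.5 TPM (log2 fold change 7.56, SE 0.43, limma adjusted p = 4.3e-07). Nfil3 (chromosome 13, 52967209 to 52981073), a transcription factor gene, rose by 6.96 (SE 0.31), and the feedback inhibitors of cytokine signalling Cish and Socs1 rose by 6.66 (SE 0.52) and 4.28 (SE 0.36). The arginine transporter gene Slc7a3 was listed at 0 in both 0 h libraries and stood at 35.3 ± 0.15 TPM at 24 h. The immediate early gene Fos (chromosome 12, 85473890 to 85477273) fell from 2248 ± 2328 to 1.45 ± 0.01 TPM (-9.29, SE 0.86, adjusted p = 2.8e-05), and the phosphatase gene Dusp1 fell by 6.08 (SE 0.66). The heat shock gene Hspa1a stood at 164 ± 62.5 TPM at 0 h and was listed at 0 at 24 h.

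Lists of cell cycle and growth genes were called higher in WT cells at 24 h. Of 41 tested genes of DNA replication and S phase 35 rose (36 adjusted over the list alone) with a median log2 change of 2.19, among them the licensing factor Cdc6 (3.90, SE 0.41) and the ribonucleotide reductase subunit Rrm2 (3.67, SE 0.61). Camera gave this list adjusted p = 6.8e-22, and adjusted p = 0.13 with an estimated correlation. Of 41 ribosome biogenesis and MYC target genes 32 rose (37 adjusted over the list alone; median 1.74, camera adjusted p = 9.5e-17, adjusted p = 0.22 with an estimated correlation), such as nucleolin, Ncl (2.19, SE 0.41). Of 24 cholesterol synthesis genes 19 rose (22 over the list alone), with a median of 2.16 and Fdps at 3.85 (SE 0.36). Camera gave adjusted p = 4.4e-14, and adjusted p = 0.13 with an estimated correlation. Among 40 mitochondrial respiratory chain genes 19 rose (30 over the list alone, median 0.89, adjusted p = 2.8e-10, adjusted p = 0.30 with an estimated correlation). Among 37 genes of the unfolded protein response 18 rose (23 over the list alone, median 1.26, adjusted p = 6.0e-08, adjusted p = 0.30 with an estimated correlation).

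Lists of resting and pan B cell genes were called lower in WT cells at 24 h. Of 35 resting B cell genes 20 fell and 1 rose (26 and 1 adjusted over the list alone), including the glucocorticoid-induced gene Tsc22d3 (-4.95, SE 0.40) and the complement receptor Cr2 (-4.48, SE 0.83). The list median was -1.78 (camera adjusted p = 1.3e-16, adjusted p = 0.096 with an estimated correlation). Of 28 pan B cell genes 9 fell (12 over the list alone, median -0.81, adjusted p = 2.5e-09, adjusted p = 0.21 with an estimated correlation), with Fcrla at -4.04 (SE 0.45) and the kinase Blk at -2.35 (SE 0.35). Of 20 immediate early and stress genes 16 fell (16 over the list alone, median -2.74, adjusted p = 3.5e-15, adjusted p = 0.13 with an estimated correlation). Of 17 markers of macrophages and monocytes 7 fell as well (11 fell and 1 rose over the list alone, median -1.27, adjusted p = 1.5e-05, adjusted p = 0.30 with an estimated correlation), and the complement gene C1qa went from 6.04 ± 0.61 TPM to a listing of 0. Of 24 IL-4 and STAT6 response genes 8 rose and 2 fell (9 and 2 over the list alone, median 0.28, adjusted p = 0.034, adjusted p = 0.42 with an estimated correlation), a call lost with the replicate block (0.056) and without WT 24 h replicate 3 (0.065). In all, limma called 1956 genes at 24 h, 1379 of them higher (70.5%, or 53.8% of 2078 after rescaling), and 3063 with the replicate block. Without WT 0 h replicate 1, WT 0 h replicate 3, WT 24 h replicate 1 or WT 24 h replicate 3 the count was 973, 1184, 811 and 1283.

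At 48 h mitotic genes rose as a group in WT cells. All 40 genes of the mitosis and G2/M list rose (40 adjusted over the list alone), with a median of 3.84, and 3.57 after rescaling, which took 0.17 off the median of all genes. Camera gave adjusted p = 5.3e-31 for it, and adjusted p = 0.082 with an estimated correlation. Cyclin B1, Ccnb1, rose from 8.02 ± 5.34 to 439 ± 2.88 TPM (5.75, SE 0.43, limma adjusted p = 2.9e-06), the ubiquitin-conjugating enzyme Ube2c by 5.53 (SE 0.48) and the kinase Plk1 by 5.17 (SE 0.40). The cytokine feedback inhibitor Socs2 rose by 7.43 (SE 0.57), the G protein-coupled receptor Gpr15 by 6.68 (SE 0.44) and the fatty acid binding protein Fabp5 by 6.46 (SE 0.56). Aicda (chromosome 6, 122553801 to 122564180, plus strand), which encodes the deaminase AID that starts class switching, rose from 6.73 ± 8.88 to 66.3 ± 1.33 TPM (3.90, SE 1.0, adjusted p = 0.013). The 0 h mean of Aicda rested on replicate 1, with 13.0 TPM from 121 reads against 0.453 TPM from 4 reads in replicate 3, and at 24 h it stood at 3.59 ± 0.538 TPM. The Aicda call at 48 h was lost without WT 0 h replicate 3 (2.26, adjusted p = 0.15), WT 48 h replicate 1 (0.062) or WT 48 h replicate 3 (0.065).

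Lists of glycolysis, histone and class switch genes were called higher in WT cells at 48 h, and pan B cell genes lower. Of 22 glycolysis genes 13 rose (15 over the list alone), with a median of 1.70 (1.43 rescaled), camera adjusted p = 3.5e-06 and adjusted p = 0.29 with an estimated correlation. Lactate dehydrogenase A, Ldha, reached 2690 ± 206 TPM from 322 ± 34.3 (3.06, SE 0.30). Of 25 replication-dependent histone genes 11 rose (13 rose and 2 fell over the list alone, median 2.22, 1.93 rescaled, adjusted p = 0.00089, adjusted p = 0.28 with an estimated correlation), with the linker histone Hist1h1b at 3.68 (SE 0.47). Of 14 TET and DNA methylation enzymes 2 rose (2 over the list alone), the maintenance methyltransferase Dnmt1 (2.02, SE 0.43) and its partner Uhrf1 (4.23, SE 0.36), while the list as a whole was not called (adjusted p = 0.24). Of 38 genes of the class switch and hypermutation machinery 17 rose and 1 fell (18 and 1 over the list alone, median 0.93, 0.68 rescaled, adjusted p = 0.00030, adjusted p = 0.49 with an estimated correlation), such as the exonuclease Exo1 (3.64, SE 0.33). Of the pan B cell genes 12 of 28 fell (18 over the list alone, median -1.29, -1.58 rescaled, adjusted p = 5.1e-12, adjusted p = 0.096 with an estimated correlation). Limma called 2659 genes, 1905 of them higher (71.6%, or 54.3% of 2869 after rescaling). Without WT 0 h replicate 1, WT 0 h replicate 3, WT 48 h replicate 1 or WT 48 h replicate 3 the count was 1707, 1750, 1717 and 1428.

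**Figure D1:**
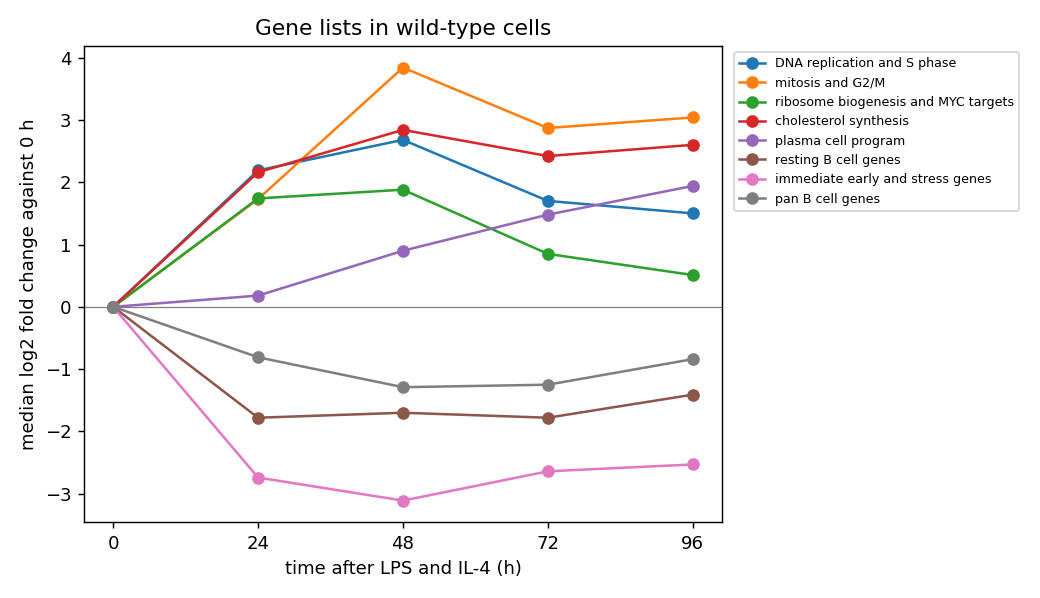
Median log2 fold change of 8 gene lists in WT cells against 0 h (vertical axis) at 24, 48, 72 and 96 h after LPS and IL-4 (horizontal axis), with 0 marking the 0 h reference. The mitosis list reached 3.84 at 48 h, the ribosome biogenesis list stood at 1.88 at 48 h and 0.51 at 96 h, and the plasma cell list stood at 0.18 at 24 h and 1.94 at 96 h.

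At 72 h plasma cell genes stood among the rises in WT cells. Of 27 genes of the plasma cell program 12 rose (14 over the list alone), with a median of 1.48, camera adjusted p = 1.7e-07 and adjusted p = 0.17 with an estimated correlation. They included Prdm1, the gene of the plasma cell regulator Blimp-1 (2.41, SE 0.40), Hid1 (3.47, SE 0.45) and the chaperone Mzb1, which rose from 632 ± 145 to 2989 ± 500 TPM (2.25, SE 0.27, limma adjusted p = 0.00010). Of 40 interferon-stimulated genes 12 rose (16 rose and 2 fell over the list alone, median 0.91, adjusted p = 2.2e-05, adjusted p = 0.41 with an estimated correlation), among them Isg15 (2.97, SE 0.48) and Gbp2 (3.22, SE 0.33). Of 26 p53 targets 10 rose and 2 fell (13 and 3 over the list alone, median 0.92, adjusted p = 0.00049, adjusted p = 0.33 with an estimated correlation), with the cell cycle inhibitor Cdkn1a at 3.32 (SE 0.45). Aicda stood at 182 ± 118 TPM (5.18, SE 1.0, adjusted p = 0.0035), and Gpr15 at 219 ± 105 TPM (7.23, SE 0.44). The costimulatory ligand Icosl fell from 226 ± 4.95 to 1.46 ± 1.03 TPM (-6.60, SE 0.47) and the adrenergic receptor Adrb2 fell by 5.91 (SE 0.46). Of 21 marginal zone B cell genes 11 fell and 2 rose (12 and 3 over the list alone, median -1.29, adjusted p = 6.1e-05, adjusted p = 0.11 with an estimated correlation), Dtx1 among them (-3.55, SE 0.35). Rn45s took 47.0% of the TPM of WT 72 h replicate 3, the highest share of any library, and the size factor was 0.675 there and 1.167 in replicate 1. Rescaling moved the median of all genes from -0.01 to 0.01. Counts with a library left out, given below, were not rescaled. Limma called 1751 genes, 927 of them higher (52.9%, or 55.6% of 2248 after rescaling), and 2858 with the replicate block. Without WT 0 h replicate 1 or replicate 3 it called 1041 and 961. The direction of the calls turned on the 72 h libraries, with 428 higher and 841 lower without WT 72 h replicate 1, and 1114 higher and 387 lower without WT 72 h replicate 3.

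At 96 h the plasma cell program was also called higher than at 0 h in WT cells. Of its 27 tested genes 17 rose (19 over the list alone), with a median of 1.94, camera adjusted p = 4.1e-10 and adjusted p = 0.11 with an estimated correlation, and Mzb1 reached 5419 ± 1042 TPM (3.10, SE 0.27). Gpr15 (chromosome 16, 58717433 to 58719070, minus strand) rose from 0.46 ± 0.64 to 362 ± 36.2 TPM (8.03, SE 0.44, limma adjusted p = 1.7e-07), and the membrane protein genes Tmem176a and Tmem176b rose by 7.15 (SE 0.54) and 6.25 (SE 0.55). Ebi3, a subunit of the cytokines IL-27 and IL-35, rose by 4.52 (SE 0.40), and Cdkn1a by 4.04 (SE 0.45). The p53 target Phlda3 was listed at 0 in both 0 h libraries and stood at 89.5 ± 36.7 TPM. Aicda stood at 327 ± 191 TPM (6.05, SE 1.0, adjusted p = 0.0012). Icosl fell by 6.23 (SE 0.47), Cr2 by 5.34 (SE 0.83) and the phosphatase gene Acp5 by 5.42 (SE 0.97). Of 37 unfolded protein response genes 20 rose (27 over the list alone, median 1.48, adjusted p = 1.4e-12, adjusted p = 0.19 with an estimated correlation). Of 41 ribosome biogenesis genes 3 rose (3 over the list alone, median 0.51, adjusted p = 0.0077, adjusted p = 0.63 with an estimated correlation), a call lost without WT 0 h replicate 1 (0.080) and turned without WT 96 h replicate 3 (0.47). Limma called 1596 genes, 1084 of them higher (67.9%, or 56.9% of 1929 after rescaling), and 2574 with the replicate block. Without WT 0 h replicate 1, WT 0 h replicate 3 or WT 96 h replicate 3 the count was 990, 917 and 1002.

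Late and early activated WT cells were compared directly at 96 h and 24 h. Jchain (chromosome 5, 88519809 to 88527891, minus strand), which encodes the chain joining secreted IgM and IgA, stood at 2325 ± 1991 TPM at 96 h against 18.9 ± 12.2 TPM at 24 h (6.69, SE 1.07, limma adjusted p = 0.0055, 0.056 without WT 24 h replicate 3). Tmem176b rose by 5.19 (SE 0.55), the small GTPase gene Rasd1 by 5.31 (SE 0.78), the Toll-like receptor Tlr12 by 5.05 (SE 0.57) and Aicda by 6.03 (SE 1.0, adjusted p = 0.0066). Aicda lost this call without WT 24 h replicate 1 (0.056), WT 24 h replicate 3 (0.053) or WT 96 h replicate 1 (0.081). The quinone reductase Nqo1 fell from 37.2 ± 23.6 to 1.04 ± 1.23 TPM (-4.22, SE 0.57). Of 27 plasma cell genes 12 rose (16 over the list alone, median 1.13, camera adjusted p = 5.8e-15, adjusted p = 0.20 with an estimated correlation), with Hid1 at 3.56 (SE 0.45). Of 40 mitosis genes 5 rose (17 over the list alone, median 1.07, adjusted p = 1.1e-14, adjusted p = 0.39 with an estimated correlation). All 41 ribosome biogenesis and MYC target genes had values below 0, and 3 of them fell (31 over the list alone, median -1.21, adjusted p = 5.1e-18, adjusted p = 0.38 with an estimated correlation). The gene Ung, whose glycosylase removes the uracil that AID makes, fell by 1.70 (SE 0.35, adjusted p = 0.022), but not without WT 24 h replicate 1 (0.18), WT 24 h replicate 3 (0.070) or WT 96 h replicate 1 (0.17). Limma called 335 genes, 247 higher and 88 lower, and 964 with the replicate block, 536 higher and 428 lower. Without WT 24 h replicate 1, WT 24 h replicate 3, WT 96 h replicate 1 or WT 96 h replicate 3 it called 72, 111, 80 and 643. The excess of higher calls turned without WT 96 h replicate 3, with 259 higher and 384 lower.

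The main question of the design was whether loss of TET2 and TET3 changed gene expression, Aicda in particular, during activation. Averaged over 24, 48, 72 and 96 h, Ccl22 was lower in DKO cells, with a log2 difference of -1.71 (SE 0.22, limma adjusted p = 0.0086), and it was lower in 8 of 8 same-numbered pairs (pair SD 0.56). It stood at 246 ± 37.5, 140 ± 34.1, 80.4 ± 47.0 and 167 ± 8.52 TPM in WT and at 120 ± 10.8, 45.2 ± 10.5, 20.2 ± 11.5 and 34.4 ± 12.1 TPM in DKO. Aicda stood at 3.59 ± 0.538, 66.3 ± 1.33, 182 ± 118 and 327 ± 191 TPM in WT and at 1.67 ± 0.798, 31.3 ± 6.64, 116 ± 72.7 and 142 ± 156 TPM in DKO. Its mean difference of -1.06 (SE 0.50) did not pass the limma test (adjusted p of 1), and of 32 other limma settings all lay below 0, from -1.43 to -0.69, and none passed (adjusted p 0.52 to 1). Aicda was lower in DKO in 8 of 8 pairs (-1.06 ± 0.65 SD), for which the exact sign-flip test chosen after the pairs had been seen gave p = 0.0078 (adjusted over 4 genes 0.016). Times of a replicate may share animals, in which case the pairs are not independent. The Ccl22 call was lost with a pseudocount of 0.1 TPM (-1.74, adjusted p = 0.15) and held with each of the 16 activated libraries left out in turn.

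**Figure D2:**
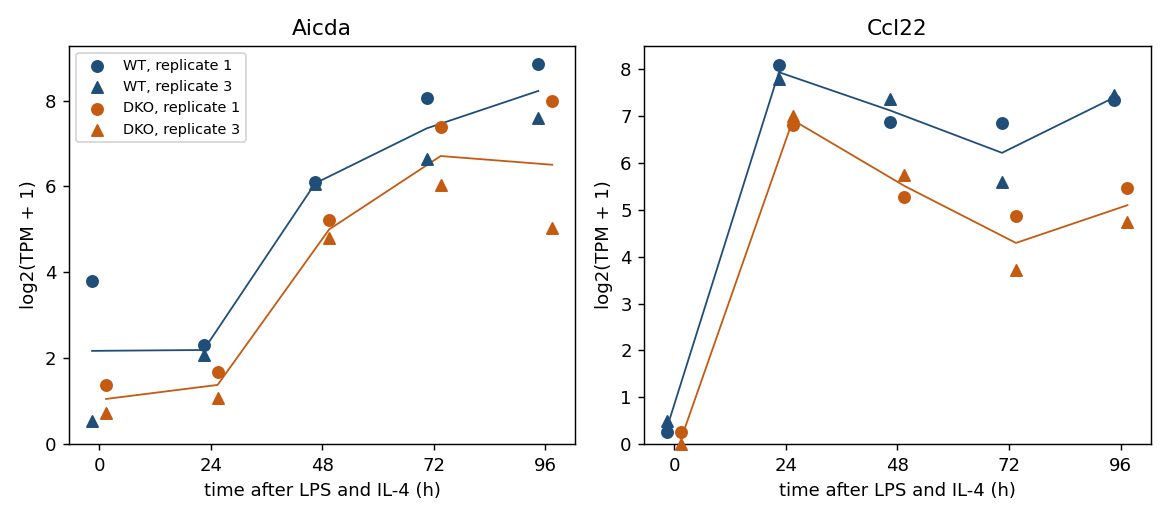
Aicda (left) and Ccl22 (right) as log2(TPM + 1) on the vertical axes against hours after LPS and IL-4, with each point a library (circles replicate 1, triangles replicate 3), WT in blue, DKO in orange, and lines through the means of the log2 values of 2 libraries. In 8 of 8 activated pairs of the same number the DKO library lies below the WT library for both genes.

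Other genes and lists were also compared between the genotypes over the activated times. The microRNA genes Mir6972 and Mir1a-2 were called higher in DKO (2.19, SE 0.11, and 0.99, SE 0.10), but neither had more than 2 reads in any library and both were listed at 0 in WT. The copper transporter Slc31a2 stood at -1.25 (SE 0.22, limma adjusted p = 0.13), and the call passed with the replicate block (0.017) and after rescaling (0.0017). It was chosen after its values had been seen, as was the reductase gene Cyb5r3 at -0.59 (adjusted p = 0.87, 0.032 after rescaling). All 41 ribosome biogenesis and MYC target genes lay above 0 with a median of 0.13 (camera adjusted p = 0.012, adjusted p = 0.95 with an estimated correlation), Gar1 at 0.46 (SE 0.24). Of 26 p53 targets 22 lay above 0 (median 0.16, adjusted p = 0.013, adjusted p = 0.95 with an estimated correlation), Cdkn1a at 0.61 (SE 0.23). Of 40 respiratory chain genes 35 lay above 0 (median 0.05, adjusted p = 0.032, adjusted p = 0.95 with an estimated correlation). No member of these 3 lists passed over all genes or adjusted over the list alone, and each list lost its call without WT 72 h replicate 3 (0.080, 0.12 and 0.080). The ribosome biogenesis list turned without WT 96 h replicate 1 (0.44), as did the respiratory chain list without DKO 96 h replicate 3 (0.97) or WT 96 h replicate 1 (0.81). The ribosome biogenesis list was also not called without DKO 72 h replicate 3 (0.17), DKO 96 h replicate 3 (0.76) or WT 24 h replicate 3 (0.060). The respiratory chain list was also not called after rescaling (0.30) or without replicate 3 of DKO at 24, 48 or 72 h (0.52, 0.23 and 0.44) or replicate 1 of WT at 24 or 48 h (0.39 and 0.23). Limma called 3 genes (1 lower in DKO), 6 with the replicate block (3 lower) and 6 after rescaling (4 lower). Voom with the block called 5, all lower. In camera the block added the lists of immediate early genes (0.030) and the unfolded protein response (0.032), both at adjusted p = 0.95 with an estimated correlation.

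At 0 h, unstimulated DKO cells were compared with unstimulated WT cells. Of 40 respiratory chain genes 37 were above 0 (median 0.32, camera adjusted p = 1.3e-09, adjusted p = 0.72 with an estimated correlation), such as Cox6c at 58.9 ± 1.03 TPM against 38.9 ± 3.35 in WT (0.59, SE 0.26). Of 40 interferon-stimulated genes 31 were above 0 (median 0.35, adjusted p = 1.3e-07, adjusted p = 0.72 with an estimated correlation), with Irf7 at 1.24 (SE 0.49) and Ifi27l2a at 1.09 (SE 0.35). Both lists lost their call without DKO 0 h replicate 3 (0.78 and 0.78). Of 40 mitosis genes 38 were below 0 (median -0.36, adjusted p = 1.3e-09, adjusted p = 0.72 with an estimated correlation), Plk1 at -1.47 (SE 0.40). Of 22 germinal centre B cell genes 20 were below 0 (median -0.35, adjusted p = 0.0016, adjusted p = 0.72 with an estimated correlation), the receptor S1pr2 at -1.45 (SE 0.54). Without WT 0 h replicate 1 these 2 lists were not called (0.21 and 0.45), and without either DKO library the germinal centre list was not called either (0.069 and 0.067). Of 41 DNA replication genes 31 were below 0 (median -0.22, adjusted p = 0.0034, adjusted p = 0.99 with an estimated correlation), a call lost without DKO 0 h replicate 1 (0.43) or WT 0 h replicate 1 (0.069).

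Markers of other cells were also compared between the genotypes at 0 h. Of 17 macrophage and monocyte markers 15 were above 0 in DKO (median 0.48, camera adjusted p = 0.0016, adjusted p = 0.72 with an estimated correlation) and of 6 neutrophil markers 5 were above 0 (median 0.29, adjusted p = 0.0018, adjusted p = 0.72 with an estimated correlation). Of the neutrophil markers 0 passed over all genes and 2 passed adjusted over the list alone. Without DKO 0 h replicate 1 the macrophage list turned (0.46) and the neutrophil list was not called (0.98), nor were they without WT 0 h replicate 3 (0.71, macrophage) and WT 0 h replicate 1 (0.28, neutrophil). The 14 TET and DNA methylation enzymes had a median of -0.38 (adjusted p = 0.060), and passed with the replicate block (0.0084) and after rescaling (-0.29, adjusted p = 0.023), at adjusted p = 0.99 with an estimated correlation. Aicda stood at 1.13 ± 0.656 TPM in DKO against 6.73 ± 8.88 in WT (-1.12, SE 1.0, adjusted p of 1), with 0.52 without WT 0 h replicate 1 and -2.75 without WT 0 h replicate 3. Limma called 2 genes at 0 h, of 200 with an unadjusted p under 0.05, which is fewer than the share expected if no gene differed. Mir7048 was listed at 0 in DKO with 1 and 2 reads in WT, and Rnf138rt1 (1.46, adjusted p = 0.017), named after its value was seen, had at most 2 reads in a library.

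Within single activated times limma called few genes between the genotypes. At 24 h limma called 0 genes and 0 lists, with 71 genes at an unadjusted p under 0.05 and 0 called by voom. In every genotype comparison the number of genes at an unadjusted p under 0.05 was below that expected if no gene differed. The fit has no term for the library set, so few calls do not show that few genes differ. At 48 h, 21 of 22 glycolysis genes and 21 of 26 p53 targets were above 0 in DKO (medians 0.23 and 0.15, camera adjusted p = 0.029 for both, adjusted p = 0.99 with an estimated correlation). The IL-4 and STAT6 list had 17 of 24 members below 0 (median -0.08, adjusted p = 0.029, adjusted p = 0.99 with an estimated correlation, 0.077 with the replicate block, 0.05 after rescaling). The glycolysis list turned without DKO 48 h replicate 1 (0.90) or WT 48 h replicate 3 (0.83), and the IL-4 list was not called without those libraries (0.79 and 0.66). The p53 list was not called without DKO 48 h replicate 3 (0.32), WT 48 h replicate 1 (0.21) or WT 48 h replicate 3 (0.079). The 1 gene called was Mir6972, listed at 0 in WT with at most 2 reads in DKO. At 72 h limma called 0 genes, with 218 at an unadjusted p under 0.05. Voom called 0 genes there, and 2 with the replicate block, both lower in DKO. The median of all genes at 72 h was 0.24 before and 0 after rescaling. Of 40 respiratory chain genes 39 were above 0 (median 0.30, 0.00 rescaled, adjusted p = 0.026, adjusted p = 1.0 with an estimated correlation). That call was lost after rescaling (0.88), without DKO 72 h replicate 3 (0.78) or without WT 72 h replicate 1 (0.10).

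At 96 h Ccl22 had a log2 difference of -2.29 between DKO and WT (SE 0.43, limma adjusted p = 0.32, 0.048 after rescaling). The median of all genes was -0.15 and moved to 0 after rescaling. Below 0 lay 36 of 37 unfolded protein response genes (median -0.40, -0.21 rescaled, camera adjusted p = 0.00063), 22 of 22 glycolysis genes (-0.49, -0.30 rescaled, adjusted p = 0.016), 24 of 24 cholesterol synthesis genes (-0.34, -0.15 rescaled, adjusted p = 0.035) and 27 of 28 pan B cell genes (-0.33, -0.16 rescaled, adjusted p = 0.048), each at adjusted p = 0.98 with an estimated correlation. The 25 histone genes had a median of -0.06 (0.12 rescaled) but a mean of 0.23, and camera called them higher (adjusted p = 0.045, adjusted p = 0.98 with an estimated correlation, 0.068 with the replicate block). After rescaling the pan B cell and histone lists were not called (0.11 and 0.15), and 2 other lists were called higher in DKO, ribosome biogenesis (median 0.20 rescaled, adjusted p = 0.047, 0.11 before) and the respiratory chain (0.18 rescaled, adjusted p = 0.022, 0.093 before), both at adjusted p = 0.98 with an estimated correlation. No member of these 5 lists passed over all genes or adjusted over the list alone. Without WT 96 h replicate 3 the unfolded protein response list turned (0.72), and the cholesterol, pan B cell and histone lists were not called (0.089, 0.069 and 0.50). Without DKO 96 h replicate 3 the glycolysis list turned (0.67) and the cholesterol, pan B cell and histone lists were not called (0.62, 0.73 and 0.18). Without DKO 96 h replicate 1 the unfolded protein response list turned (0.29) and the histone list was not called (0.20). Without WT 96 h replicate 1 the glycolysis list turned (0.12) and the cholesterol and pan B cell lists were not called (0.25 and 0.49). Limma called 2 genes, Mir6972 and Mir1a-2, both listed at 0 in WT with at most 1 read in DKO, of 214 genes at an unadjusted p under 0.05. Voom called 0 genes there, and 2 with the replicate block, both lower in DKO.

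The last comparison asked whether the genotype difference changed from 0 h to the activated times. Aicda gave 0.06 (SE 1.12, limma adjusted p of 1), with -1.58 without WT 0 h replicate 1 and 1.69 without WT 0 h replicate 3. The median of all genes was 0.11 before and 0 after rescaling. Of 40 mitosis genes 38 lay above 0 (median 0.46, 0.37 rescaled, camera adjusted p = 1.8e-07), as did 34 of 41 DNA replication genes (0.27, 0.16 rescaled, adjusted p = 0.00093), both at adjusted p = 1.0 with an estimated correlation. Of 22 germinal centre genes 20 lay above 0 (0.23, 0.08 rescaled, adjusted p = 0.026), at adjusted p = 1.0 with an estimated correlation. That call was also lost with the replicate block (0.054) and after rescaling (0.081). Of 40 interferon-stimulated genes 30 lay below 0 (median -0.19, -0.34 rescaled, adjusted p = 3.4e-06), as did 34 of 40 respiratory chain genes (-0.20, -0.36 rescaled, adjusted p = 3.9e-06), both at adjusted p = 1.0 with an estimated correlation. Among the markers of other cells 13 of 17 macrophage genes (-0.39, -0.50 rescaled, adjusted p = 0.0038) and 5 of 6 neutrophil genes (-0.42, -0.39 rescaled, adjusted p = 0.00089) lay below 0, at adjusted p = 1.0 with an estimated correlation. No member of these 7 lists passed over all genes or adjusted over the list alone. Each list lost its call without at least 1 of the 0 h libraries. Without DKO 0 h replicate 3 the respiratory chain list turned (0.89) and the interferon list was not called (0.95), and without WT 0 h replicate 1 the mitosis and germinal centre lists were not called (0.42 and 0.81). Without DKO 0 h replicate 1 the macrophage list turned (0.38) and the DNA replication and neutrophil lists were not called (0.30 and 0.84). The macrophage list was also not called without WT 0 h replicate 3 (0.76) or WT 72 h replicate 3 (0.064) or with a pseudocount of 0.1 TPM (0.072), nor was the neutrophil list without WT 0 h replicate 1 (0.18). The germinal centre list was not called without either DKO 0 h library (0.16 and 0.32), with the TopHat table (0.067) or with a pseudocount of 0.1 TPM (0.072), nor without any of 6 activated libraries (0.053 to 0.086). The tight junction gene Cldn13 was called at -3.44 (SE 0.41, adjusted p = 0.0039), from 0 reads in WT and 3 and 7 reads in DKO at 0 h to 18 and 17 reads in WT and 7 and 5 reads in DKO at 96 h. Limma called 3 other genes, Mir7048 (4.86), Mir6972 (2.19) and Rnf138rt1 (-1.46), each with at most 2 reads in any library. They were the 4 called of 154 genes with an unadjusted p under 0.05, and voom called 0 genes, or 1 with the replicate block. The TET and DNA methylation list was not called (median 0.41, adjusted p = 0.11), and passed with the replicate block (0.021) and after rescaling (0.30, adjusted p = 0.043), at adjusted p = 1.0 with an estimated correlation.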

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

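The counts over other splits of the libraries were planned before the result was seen. The tests on microRNA reads and on Aicda at 0 h were chosen after the results had been seen.

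The genotype difference over the activated times differed from that at 0 h for 4 genes and 7 gene lists, by a limma contrast or camera test of the change itself. Mir7048 gave 4.86 and Mir6972 gave 2.19 on the log2 scale, and the highest number of reads of a called microRNA gene in any library was 2. Cldn13 gave -3.44 with at most 21 reads in a library, and Rnf138rt1, named after its value was seen, gave -1.46 with at most 2 reads. The adjusted p of camera was 1.8e-07 for mitosis and G2/M (38 of 40 members above 0), 0.00093 for DNA replication and S phase (34 of 41 above 0) and 0.026 for germinal centre B cell genes (20 of 22 above 0). It was 3.4e-06 for interferon-stimulated genes (30 of 40 below 0) and 3.9e-06 for the mitochondrial respiratory chain (34 of 40 below 0). It was 0.0038 for macrophage and monocyte markers (13 of 17 below 0) and 0.00089 for neutrophil markers (5 of 6 below 0). All 7 list calls were lost at adjusted p = 1.0 with an estimated correlation. They were also lost in turn without single 0 h libraries. Without WT 0 h replicate 1 the mitosis, germinal centre and neutrophil calls were lost. Without DKO 0 h replicate 1 the DNA replication, macrophage, neutrophil and germinal centre calls were lost. Without DKO 0 h replicate 3 the interferon, respiratory chain and germinal centre calls were lost, and without WT 0 h replicate 3 the macrophage call.

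Splits of the libraries within each time gave counts as large as the genotype comparisons. For DKO against WT over the activated times, 35 of 100 splits called at least the 3 genes of the real one, with up to 1387 genes in another split. For the change from 0 h, 42 of 100 splits called at least 4 genes, with up to 2701 in another. For the change, each split that set the 2 library sets against each other at 0 h called 26 genes or more. The other splits that reached 4 genes kept the libraries of each genotype together at 0 h. Splits that mixed genotypes and library sets at 0 h called at most 3. The count of 42 is therefore not a test of chance alone, and chance was not excluded for either count. The 2 splits of the activated times with over 700 genes kept same-numbered libraries together at all times or all but 1, which set the 2 library sets against each other. Among the 17 splits that parted all same-numbered pairs, as the genotypes do, the real one alone reached 3 genes over the activated times (highest other 2). Among 7 such splits for the change from 0 h, 2 reached 4 genes (highest other 4), the real one and one that kept the genotypes as labelled at 0 h.

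Aicda stood at 13.0 TPM (121 reads) in the WT 0 h replicate 1 library and at 0.453 to 1.59 TPM in the other 0 h libraries. Cells or reads from the WT 96 h replicate 1 culture were argued against by 7 genes of that culture that the other 0 h libraries lacked. In WT 0 h replicate 1 these genes stood at a median of 0.122% of their level in that culture (3 of them at 0 reads, highest 2.35%), against 2.82% for Aicda. Cultures of other times, of DKO cells or of replicate 3 were not tested as a source. Germinal centre B cells in that sample may be a candidate source: the germinal centre list without Aicda was higher than in the DKO library of the same number, with a median of 0.19 at percentile 99.86 of 10000 matched random lists (16 of 21 members higher), and the mitosis list with a median of 0.62 at percentile 100 (39 of 40). In replicate 3 the germinal centre list stood at 0.35 and percentile 96.12 (15 of 21 higher) and mitosis at 0.23 and percentile 77.28, although Aicda was low there. Genes of the random lists were drawn singly, so the percentiles ignore correlation within a list, estimated at 0.29 and 0.57 for the 2 full lists. With that correlation camera gave both adjusted p = 0.72 at 0 h. Both had already been seen to lie lower in DKO at 0 h, so the percentiles are not independent support for this source. A genotype difference stays open, because the ratio of DKO to WT reads in replicate 3 was 1.51 from 7 and 4 reads in 1 library of each genotype, which is too few to decide.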

How the results depend on the processing

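Rescaling with the block, the filter of at least 10 reads, voom with and without the block, and the sign-flip test were chosen after the data had been seen. The cause of the changes below was not tested unless stated.

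Most of the single genes and lists followed kept their direction and their side of the threshold, but no list kept its call with an estimated correlation. For genes, the same side includes results that passed in neither fit. Counts of called genes and lists, and Aicda over the activated times, are not in this tally. Over all settings, single genes gave 2928 results on the same side, 26 that passed only in the alternative, 245 that passed only in the fit reported, and 27 that turned. Gene lists gave 1088 on the same side, 256 called only in the fit reported and 14 that turned. This tally follows the lists called in the fit reported and leaves out lists that only an alternative called. Genotype comparisons at single times were limited by 2 libraries per group and, in the fit reported, by the absence of the block. In a self-test at 48 h limma found 0 of 100 genes changed 2-fold and 2 of 100 changed 4-fold (1 and 39 with the replicate block). Over the activated times it found 52 and 92 of 100 (68 and 96 with the block). Where 1 library was left out, the lone library was assumed to vary like those of the other groups. Fits with only the samples compared had 2 libraries on each side at a single time and so few residual degrees of freedom, which lowers their counts.

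Counts of genes between DKO and WT moved with the pseudocount and the filter. With a pseudocount of 0.1 TPM limma called 4 genes at 0 h and 1 over the activated times, and with 5 TPM it called 6 over the activated times. With no filter it called 13 genes at 0 h, 1 at 24 h, 3 at 48 h, 17 at 96 h, 11 over the activated times and 15 for the change from 0 h. With a filter at TPM 5 it called 1 at 0 h and 2 for the change from 0 h. With at least 10 reads limma called 1 gene over the activated times and 1 for the change from 0 h. It called 0 at 0 h, 48 h and 96 h, since that filter drops the genes with few reads. In the fit reported 200 genes at 0 h and 214 at 96 h had an unadjusted p under 0.05. Voom called 0 genes at both times without the block, and 1 and 2 with it.

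Scaling and the variance model moved other counts. Rescaling and quantile normalization each gave 6 genes over the activated times, and quantile normalization gave 2639 genes in WT at 72 h and 509 at 96 h against 24 h. Library weights gave 1 gene at 0 h, 2 at 48 h, 2 for the change from 0 h, and 1014 in WT at 72 h. With only the samples compared limma called 1554 genes in WT at 48 h and 0 in WT at 24, 72 and 96 h. It also called 0 at 96 h against 24 h, and 0 between the genotypes at 0, 48 and 96 h. In the fit reported 200 genes had an unadjusted p under 0.05 at 0 h and 214 at 96 h. Voom without the block called 0 genes between the genotypes at 0 h, 48 h and 96 h and 0 for the change from 0 h. Limma on TPM had 200, 214 and 154 genes at an unadjusted p under 0.05 at 0 h, 96 h and for the change.

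The replicate block raised the gene counts of the WT comparisons and of the genotypes over the activated times, left the other 6 gene counts unchanged, and raised 2 of 12 list counts and lowered 3. It gave 6 genes and 5 lists over the activated times, and 3063, 2858 and 2574 genes in WT at 24, 72 and 96 h and 964 at 96 h against 24 h. Of single genes it called Slc31a2 (0.017) and Cldn13 (-1.19, adjusted p = 0.020) over the activated times. It also ended the call of the list of mast cell, basophil and platelet markers in WT at 48 h (0.060), a call that an estimated correlation ended too. The block called the plasma cell program there (0.049, against 0.077 without the block and 0.56 with an estimated correlation). Apart from the values printed here and in the results above, the block changed no call of a list, or of a gene in a comparison it is named for. Rescaled with the block, limma called 5 genes at 0 h, 2 at 48 h, 9 over the activated times, and 3977, 4661, 3981 and 3445 in WT at 24, 48, 72 and 96 h and 1847 at 96 h against 24 h. Voom with the block called 1 gene at 0 h, 0 at 48 h, 2 at 72 h, 2 at 96 h and 5 over the activated times, all lower in DKO. The 2 at 96 h were therefore not the 2 of the fit reported, which were higher in DKO. For the change from 0 h voom with the block called 1 gene, higher. In WT it called 4302, 4965, 4120 and 3488 at 24, 48, 72 and 96 h, and 2099 at 96 h against 24 h. The exact sign-flip test passed Aicda over the activated times at the same difference of -1.06, and limma did not.

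Gene list counts moved as well. With an estimated correlation camera called 0 lists in all 11 comparisons that had called lists. Fry, a rotation test that does not compare a list with other genes, called 0 lists in the 6 genotype comparisons that had any. In WT against 0 h fry called 16, 19, 19 and 15 lists at 24, 48, 72 and 96 h, where camera called 19, 16, 19 and 18. At 96 h against 24 h in WT fry called 4 lists and camera 12. The TopHat table gave 2 lists between the genotypes at 72 h and 3 at 96 h. Rescaling gave 0 lists at 72 h, where limma on single genes had 218 at an unadjusted p under 0.05 and voom called 0 (2 with the block). In WT, rescaling ended the calls of the respiratory chain at 96 h (0.076) and of mast cell, basophil and platelet markers at 48 h (0.12), and called the class switch machinery lower at 96 h against 24 h (0.043, and 0.85 with an estimated correlation). A pseudocount of 5 TPM gave 3 lists at 96 h, and one of 0.1 TPM gave 5 over the activated times.

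Some results for Aicda and Tet2 turned, none of which had passed the limma test. The Aicda change from 0 h to the activated times between the genotypes went to -0.09 with the TopHat table, -0.21 with a pseudocount of 5 TPM and -0.03 after rescaling with or without the block. Aicda in WT at 24 h went to -0.21 with a pseudocount of 5 TPM, -0.09 after rescaling with or without the block, -0.06 after quantile normalization and -0.49 with voom and the block. Leaving out libraries gave ranges of -1.58 to 1.69 for the first and -1.61 to 1.65 for the second. It gave -2.75 to 0.52 for Aicda at 0 h, -1.43 to -0.69 for Aicda over the activated times, -1.54 to 0.53 for Tet2 at 0 h and -0.10 to 0.41 for Tet2 over the activated times.

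Leaving out single libraries also moved counts. Between the genotypes limma called 1 to 4 genes at 0 h, 0 to 4 at 24 h, 1 to 2 at 48 h, 0 to 1 at 72 h, 2 to 7 at 96 h, 3 to 7 over the activated times and 3 to 5 for the change from 0 h (71 and 218 genes at an unadjusted p under 0.05 at 24 and 72 h, where voom called 0). In WT the ranges were 811 to 1283 at 24 h, 1428 to 1750 at 48 h, 961 to 1501 at 72 h, 917 to 1227 at 96 h and 72 to 643 at 96 h against 24 h. Lists ranged from 3 to 9 at 0 h, 0 to 2 at 24 h, 3 to 4 at 48 h, 1 to 5 at 72 h, 2 to 8 at 96 h, 0 to 8 over the activated times and 3 to 9 for the change, with limma and voom as above. In WT they ranged from 18 to 21 at 24 h, 15 to 17 at 48 h, 18 to 20 at 72 h, 17 to 19 at 96 h and 10 to 15 at 96 h against 24 h.

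Adjusted camera p of lists that turned ranged widely over the libraries left out. The macrophage list ranged from 3.1e-20 to 0.71 at 0 h and from 3.3e-19 to 0.76 for the change from 0 h. Glycolysis ranged from 7.5e-07 to 0.90 at 48 h and from 2.8e-10 to 0.67 at 96 h, and the unfolded protein response from 1.4e-16 to 0.72 at 96 h. The respiratory chain ranged from 7.9e-07 to 0.97 over the activated times and from 1.0e-08 to 0.89 for the change, and ribosome biogenesis from 1.9e-15 to 0.76 over the activated times. In WT, ribosome biogenesis at 96 h ranged from 1.2e-09 to 0.47 and the unfolded protein response at 96 h against 24 h from 4.4e-08 to 0.99.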

Other observations

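The tests on the library sets and on the IL-4 list without Ccl22 were chosen after the results had been seen.

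Some cell type and gene class lists were called in no comparison. T cell markers (7 tested) had a lowest camera adjusted p of 0.20, imprinted genes (11 tested) 0.15, NK cell markers (5 tested) 0.087 and the genes of B1 and memory-like B cells (19 tested) 0.080. In WT cells at 96 h against 0 h, 3 genes of B1 and memory-like B cells rose and 4 fell (5 and 4 adjusted over the list alone), with a median of -0.63. Of the NK cell markers, Il2rb, the IL-2 receptor beta chain, stood at 2.20 ± 0.75 TPM in DKO and 6.22 ± 4.40 TPM in WT over the activated times (SD over 8 libraries, log2 difference -0.95, SE 0.23, limma adjusted p = 0.87), and adjusted over the list alone 1 member of this list was lower. At 96 h against 24 h in WT cells, 2 of 9 dendritic cell markers rose (3 over the list alone, median 0.99, camera adjusted p = 0.0028, adjusted p = 0.38 with an estimated correlation). They were Flt3 (3.68, SE 0.80) and Cox6a2 (3.45, SE 0.69). Both calls were lost without WT 24 h replicate 1 (0.14 and 0.070), WT 24 h replicate 3 (0.14 and 0.13) or WT 96 h replicate 1 (0.30 and 0.071), and that of Cox6a2 also without WT 96 h replicate 3 (0.059).

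The 2 library sets differed in 4510 of 11544 genes (39.1%), with 3417 higher in replicate 1 and 1093 higher in replicate 3. These counts are from TPM without rescaling. Size factors were higher in replicate 1 in most groups, such as 1.167 against 0.675 in WT at 72 h. The excess of genes higher in replicate 1 therefore cannot be told apart from a shift in scale by these counts. Xist was 3.9 to 21.9 times higher in replicate 1 within groups, and Malat1 2.6 to 6.2 times. For Xist alone, genomic DNA was argued against by its extra TPM, at least 939 times the 95th percentile of genes silent in replicate 3. Xist was already seen to differ, so this does not test genomic DNA as a source for the other genes. DKO 96 h replicate 1 had 17519 genes with a read, against at most 14336 in the other libraries, and the highest silent-gene percentile (0.261 TPM). The number of reads was argued against by replicate 1 having more reads in 6 of 10 groups only. Unspliced or nuclear RNA stays open. All 5 nuclear RNAs tested (Xist, Malat1, Neat1, Tsix and Kcnq1ot1) were higher in replicate 1 in each of 10 groups. Tsix is antisense to Xist and cannot be told apart from it without strand, so these 5 are not independent. The Spearman correlation across genes between gene length and the difference ranged from 0.05 to 0.32. The labels name the sets differently, so a difference in library preparation or animals stays open and was not tested.

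Ccl22 was lower in DKO over the activated times, and a weaker response to IL-4 as a whole could be a candidate explanation. The IL-4 and STAT6 list without Ccl22 (23 members) had a median of -0.01 with 14 members below 0, at a camera value of 0.19 before adjustment. This decides nothing either way, and an effect on Ccl22 alone stays open.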
